A study of Homo sapiens with 6 samples.

How the data were processed

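Total RNA from the SKBR3 human breast cancer cell line was hybridised, as biotin-labelled cRNA, to Illumina bead arrays, on which each probe reports the abundance of a transcript as the brightness of its beads. Per the labels, 3 arrays carried RNA from control cells, whose titles name GFP, and 3 carried RNA from cells overexpressing CDCP1. All 6 arrays share 1 slide barcode, so slide and group are not confounded. The titles number the samples of each group as experiments 1 to 3, and nothing in the labels says whether these were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

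The authors read the arrays with GenomeStudio, per the submitters' processing notes, with no version given. Both deposited tables hold values for 47231 probes on 6 arrays, and 0 probes differed between the 2 tables, although one of them is named as non-normalized. The values the authors deposited are log2 probe signals, put on a log scale and normalized between arrays before they were deposited, as the values themselves show. They ran from 6.45 to 14.35. This range is that of log2 fluorescence from a scanner, and it is too high for a log10 or natural log of such a signal. A variance-stabilising transform close to log2 cannot be excluded, so a fold stated here is exact only if the scale is log2. The authors had already brought the arrays to nearly the same distribution: the array medians lay within 0.000523 of each other, and values of the same rank differed between arrays by at most 0.139. The normalization method is not given in the sources used here. The deposited values had not been background-subtracted to a zero level, since the dimmest probes lay in a peak at 6.62, and differences of dim probes are therefore compressed.

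The analysis planned before the data were examined started from raw signals with detection p-values (neqc in limma), took 1 probe per gene and tested 35 gene lists and the CDCP1 transcript itself. The files used here hold neither detection p-values nor gene names, and no table pairing these probes with genes was used. The authors' normalization was therefore kept, each probe was tested on its own, results are given by probe ID, and the gene lists and the CDCP1 transcript were not analysed here. The overexpression label was thus not checked.

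In place of detection p-values, a background level was estimated from the values after the files had been seen. The mode of all values (6.62, kernel density with a bandwidth of 0.01) and the root mean square distance of the values below the mode (0.0408) were taken as the centre and SD of the background. A probe counted as above background on an array if it lay more than 1.645 of these SDs above the mode, a limit of 6.68. Probes above that limit on at least 3 of the 6 arrays were tested. These were 31456 probes (66.6%), and 15775 were left out. The limit is lenient, since transcripts that are absent and transcripts that are weak overlap near the mode.

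The comparison, CDCP1 minus GFP control, was fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3), without an intensity trend and without a block, over all 6 arrays. The test was two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. The number of arrays limits the precision: the median SE of a log2 change was 0.0706, and the median half-width of its 95% interval was 0.155. The fit was tested on simulated data with the same 31456 probes and the prior variance of this comparison. Of 67 probes changed by 0.3 on the log2 scale, 23.9% were called, of 67 changed by 0.5 88.1% were called, and of 66 changed by 1 100% were called. In that simulation 5 of the 146 calls, or 3.42%, were false. Only 200 of the 31456 simulated probes were changed, while 1656 were called in the real data. The Benjamini-Hochberg cut-off depends on the share of changed probes, so the shares called need not hold for the real data. The simulated noise was normal, independent between arrays and equal in both groups, as the fit assumes. In the real data the within-group SD of the CDCP1 arrays was 1.36 times that of the controls. The simulation therefore describes the fit under its own assumptions, and it does not give the error rate of the real calls.

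The planned rule named genes by size of change among probes past the threshold whose 2 groups did not overlap. It was applied to probes and limited to 2 in each direction, since their genes were not identified here. A probe that was not above background on any array of a group has only a bound there. Its fold is given as "at least", from the bright group's mean log2 value minus the dim group's mean of, per array, the higher of the lowest signal above the limit and the probe's own signal. The experiment numbers were checked for pairing through the correlation of same-numbered arrays' deviations from their group means, which was -0.27, -0.30 and 0.16. The numbers were not treated as pairing the samples.

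Alternatives were another background treatment, other scalings between arrays, stricter and no filters on dim probes, a trend and robust variance model, array weights, the experiment number as a block, the position on the slide as a covariate, other thresholds, the other deposited table, and leaving out each array in turn. A filter at 3 background SDs was added after the data had been seen.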

Results

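Gene expression was measured in SKBR3 cells, an established human breast cancer line with amplified HER2 (ERBB2), a receptor tyrosine kinase. Per the labels, the cells overexpressed CDCP1 or served as the GFP control. CDCP1 (CUB domain-containing protein 1) is a transmembrane glycoprotein phosphorylated by SRC family kinases, and GFP is a fluorescent protein with no signalling role of its own. There were 3 arrays in each group. The study set CDCP1 beside HER2 in tumour growth and trastuzumab resistance, and the arrays address which transcripts differ when CDCP1 is raised. The arrays were equally bright after the authors' processing: between 30821 and 30843 probes of 47231, or 65.3% on each array, lay above the estimated background. Arrays already brought to nearly the same distribution give such near-equal counts under a common limit, so this does not compare their quality.

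Arrays of different groups differed more than arrays of the same group, except for pairs of CDCP1 arrays that included CDCP1 replicate 1, which differed as much as pairs across groups. Over the 31456 tested probes, the SD of the log2 difference was 0.119 to 0.139 for pairs of GFP control arrays, 0.129 to 0.197 for pairs of CDCP1 arrays and 0.153 to 0.235 for pairs across groups. Pearson's r across probes, which are not independent replicates, was 0.995 to 0.997 within the controls, 0.991 to 0.996 within the CDCP1 group and 0.987 to 0.994 between them. The closest pair of arrays, GFP control replicates 2 and 3 (SD 0.119), was not set apart from the next closest (0.122), so all 6 arrays were counted. The first principal component held 46.5% of the variance. The GFP control arrays scored -13.7, -9.67 and -13.6 on it, and the CDCP1 arrays scored 23.8, 10.9 and 2.20.

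**Figure D1:**
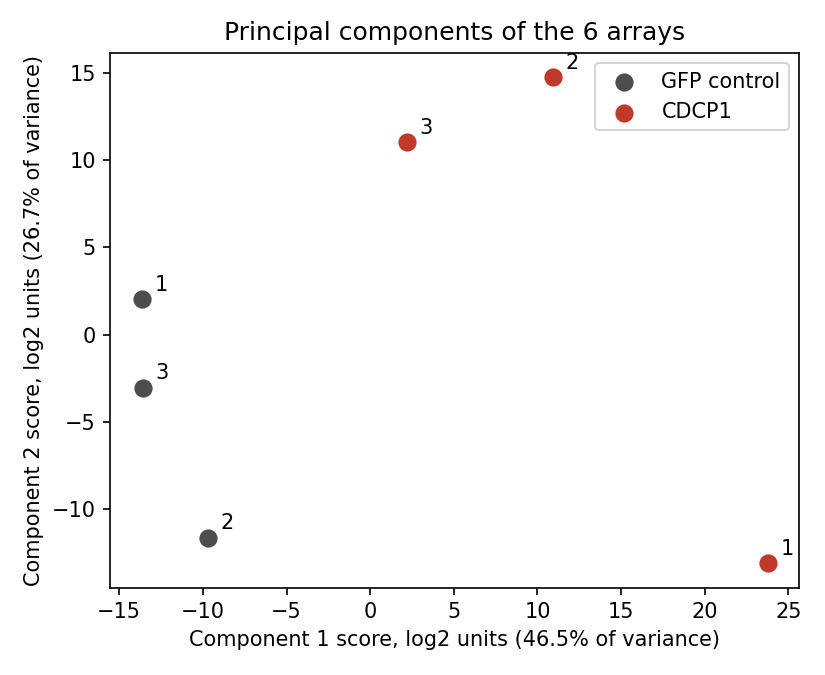
Principal components of the 6 arrays over the 31456 tested probes, with the scores of component 1 (46.5% of the variance) on the x axis and component 2 (26.7%) on the y axis, in log2 units. Each point is an array, numbered by replicate within its group; the 3 controls lie left of the 3 CDCP1 arrays, and CDCP1 replicate 1 lies apart from CDCP1 replicates 2 and 3 on component 2.

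The within-group spread was larger among the CDCP1 arrays. The root mean within-group variance over tested probes was 0.123 in the CDCP1 group and 0.0899 in the controls, a ratio of 1.36, which was not tested. A within-group SD above 0.5 was seen for 79 probes in the CDCP1 group and 23 in the controls. In 69 of the 79, replicate 1 was the CDCP1 array farthest from the group's median. The ratio of the within-group SDs was 1.01 without CDCP1 replicate 1.

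Between the cells labelled as overexpressing CDCP1 and the control, 1656 probes passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, or 5.26% of those tested. Of these, 824 were higher and 832 were lower in the CDCP1 cells, so 49.8% of the calls were higher. The median log2 change over all tested probes was -0.00408. The arrays had been brought to nearly the same distribution beforehand, which holds this median near 0 and favours an even split of calls. A shift of most transcripts in the same direction could therefore not be seen. Most changes were small. The median fold was 1.30 among the higher probes and 1.29 among the lower ones. A change of at least 1.5-fold was seen for 110 of the higher and 89 of the lower probes, and a change of at least 2-fold for 21 higher and 10 lower ones. All 1656 called probes had groups that did not overlap, all 3 CDCP1 values lying beyond all 3 control values. Among all tested probes the groups did not overlap in 6919, or 22.0%, against 10% for a random split. At an unadjusted p under 0.05 there were 5382 probes, against 1573 by chance. The count of calls varied with single arrays: it was 771, 689 and 613 without GFP control replicate 1, 2 or 3, and 710 without CDCP1 replicate 2. It was 2132 without CDCP1 replicate 1 and 1878 without CDCP1 replicate 3. With array weights in limma it was 2613.

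**Figure D2:**
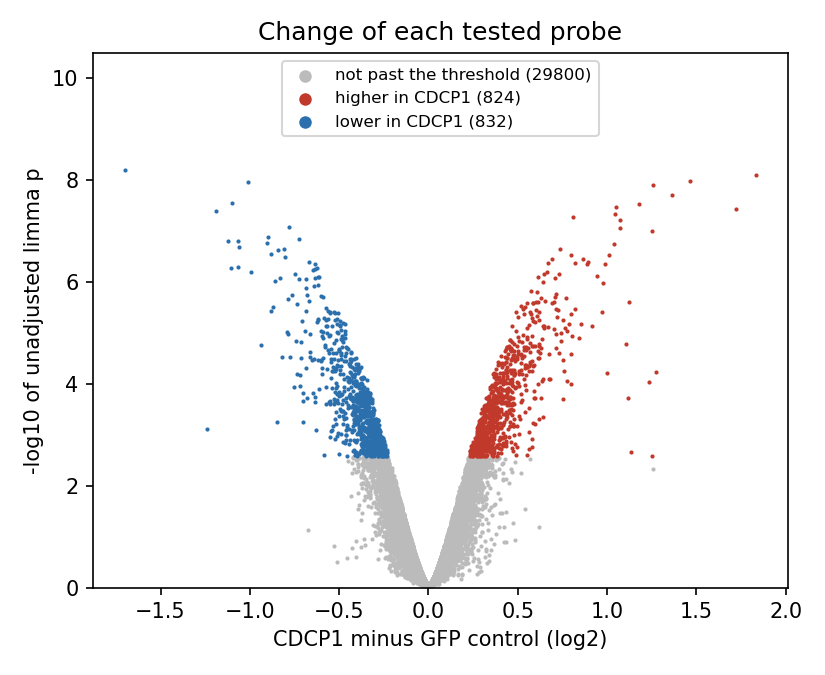
Change of each of the 31456 tested probes, as CDCP1 minus GFP control in log2 units on the x axis against the negative log10 of the unadjusted limma p on the y axis. Each point is a probe; the 824 higher (red) and 832 lower (blue) probes past the adjusted threshold of 0.05 lie on both sides in similar numbers, and the grey probes did not pass.

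Among the higher probes, ILMN_2341611 had the largest fitted log2 change. Its mean log2 signal was 6.82 ± 0.13 (SD, n = 3) in the control and 8.65 ± 0.27 (SD, n = 3) in the CDCP1 cells. Its log2 change was 1.83 (SE 0.12, 95% interval 1.57 to 2.09, limma adjusted p = 7.76e-05), or 3.56-fold higher. Of the control arrays, 2 were above background for this probe. The next was ILMN_1688670, which lay below the background limit on all 3 control arrays, with a mean of 6.61 ± 0.013 (SD, n = 3). In the CDCP1 cells it reached 8.33 ± 0.33 (SD, n = 3). It was at least 3.12-fold higher in the CDCP1 cells (limma adjusted p = 0.000117). Because this is a bound, the order of these 2 probes by size of change is not settled.

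Among the lower probes, ILMN_1733847 had the largest fitted change, with a mean log2 signal of 8.63 ± 0.12 (SD, n = 3) in the control and 6.93 ± 0.24 (SD, n = 3) in the CDCP1 cells. It changed by -1.70 on the log2 scale (SE 0.11, 95% interval -1.94 to -1.46, limma adjusted p = 7.76e-05), or 3.25-fold lower. Its CDCP1 values of 6.80, 6.78 and 7.20 lay near the background limit of 6.68, where differences are compressed, so this fold may be too small. With another background treatment (normexp with an offset of 50) its log2 change was -2.14, outside that interval. The next was ILMN_1656129, at 10.42 ± 0.099 (SD, n = 3) in the control and 9.18 ± 0.75 (SD, n = 3) in the CDCP1 cells. Its log2 change was -1.24 (SE 0.27, 95% interval -1.83 to -0.65, limma adjusted p = 0.0227). Its CDCP1 values were uneven: replicates 1 and 2 stood at 8.75 and replicate 3 at 10.05. Its adjusted p in limma was 0.0855, 0.0886 and 0.0843 without GFP control replicate 1, 2 or 3, and 0.104 without CDCP1 replicate 2, with log2 changes of -1.19, -1.24, -1.29 and -1.02. It stayed past the threshold without CDCP1 replicate 1 (log2 change -1.02, limma adjusted p = 0.026) and without CDCP1 replicate 3 (log2 change -1.67, limma adjusted p = 3.87e-06). It was also not called with an intensity trend and robust variances (adjusted p = 0.26) or without a filter on dim probes (adjusted p = 0.0976). The genes of these 4 probes were not identified here.

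**Figure D3:**
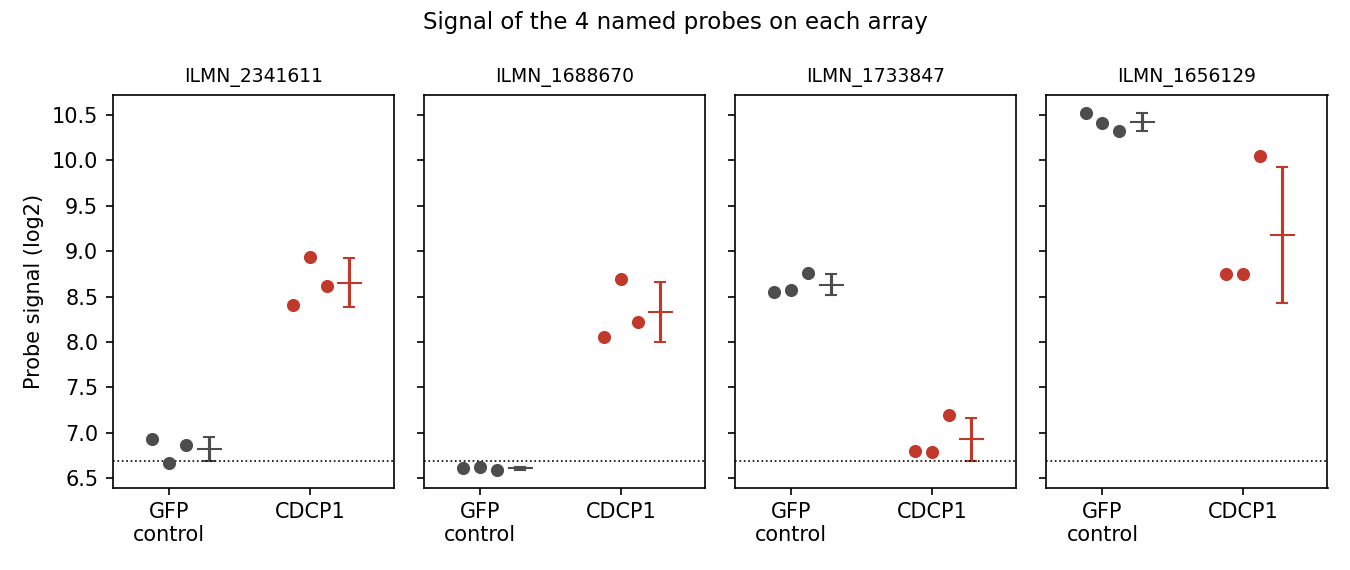
Log2 signal of the 4 named probes on each array (y axis), with GFP control in grey and CDCP1 in red. Points are the 3 arrays of a group, bars beside them are the mean ± SD, and the dotted line is the background limit of 6.68; the groups do not overlap for any of the 4 probes, and ILMN_1688670 lies below the limit in all 3 controls.

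Most calls were among the brighter probes. The tested probes were divided by their mean signal over all 6 arrays into 3 bands of nearly equal size, so a dim probe that rose strongly falls in a brighter band. In the brightest band (log2 7.75 to 14.23), 623 were higher and 613 were lower, or 11.8% of 10485. In the middle band (6.83 to 7.75), 199 were higher and 213 were lower, or 3.93% of 10485. In the dimmest band (6.63 to 6.83), 2 were higher and 6 were lower, or 0.0763% of 10486. The median SE of the log2 change was similar in the dimmest and brightest bands, at 0.067 and 0.0754. The fit had no intensity trend and drew the variances of all probes toward a shared value. These SEs therefore cannot compare precision between the bands. Differences of dim probes are compressed near background, so few calls in the dimmest band do not show that their transcripts changed less.

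Few transcripts could be called present in one group alone. There were 163 probes above background on all 3 CDCP1 arrays and on none of the controls, of which 4 passed the limma threshold. There were 127 probes with the opposite pattern, of which 1 passed. For the 18 other choices of 3 arrays from the 6, which mix the groups, the median count was 126 and the highest was 164. Neither count exceeded that highest value. The CDCP1 count lay close to it, and the control count lay close to the median. With 1 array left out and the background limit kept, the rule is looser and the counts were between 310 and 490 in CDCP1 alone and between 280 and 331 in the control alone. In each of these cases at least 1 of 9 other choices of as many arrays gave a count as large. It was 1 or 2 of 9 for CDCP1 alone, and 1 to 7 of 9 for the control alone.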

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

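The count of 1656 called probes stayed within 1.5 times, and its share of higher calls between 47.7% and 51.4%, under the alternatives that follow. These were quantile scaling (1643), normexp with an offset of 50 (1287), median scaling (1653), cyclic loess (1664), the stricter filter (1602) and no filter (1340). They were also the trend and robust variance model (1575), the slide position as a covariate (1541) and the added filter at 3 background SDs (1635). That added filter, and the background level behind the stricter filter, were set after seeing the data. Each of these shared at least 1253 probes with the 1656, the fewest under normexp. The other deposited table held the same values and tests nothing, and quantile and median scaling of already normalized arrays test little. Testing every probe of a gene was already done for the probes above background. The count was 2613 with array weights, which gave CDCP1 replicate 1 a weight of 0.381, and 1085 with the experiment number as a replicate block; the cause was not tested. It was 199 with a 1.5-fold limit and 556 at an adjusted p under 0.01, as fewer probes meet a stricter rule. Leaving out 1 array gave 613 to 2132 probes. The experiment numbers give only a hint about the block: CDCP1 replicates 1 and 2 deviated most closely with controls 2 and 1 (r across probes 0.38 and 0.29), and only replicate 3 did so with its own number (0.16). The 4 named probes kept their direction in all 70 values computed, which include those of the other deposited table. They had been chosen for large changes without overlap between groups, so leaving out 1 array could not reverse them. The stricter filter removed ILMN_2341611 and ILMN_1688670 from the test, so they have no value there. Where tested, all except ILMN_1656129 (6 calls lost) stayed past the threshold, and the block lost none of the 4. The gene lists, the CDCP1 transcript and 1 probe per gene were not run, since probes were not paired with genes. Signal over background limits the dimmest probes: normexp, which removes part of the background, gave ILMN_1733847, above background on all 6 arrays, a log2 change of -2.14 in place of -1.70.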

Other observations

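Of the tests in this part, the count over other splits was chosen after the count of called probes had been seen, and the other 3 were set before their results were computed, although the pattern they address had been seen.

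CDCP1 replicate 1 lay farthest from its group: the SD of its difference from the mean of the other CDCP1 arrays was 0.18, against 0.126 for replicate 2 and 0.138 for replicate 3, and 0.099 to 0.116 for the controls, and in 65 of the 79 probes that varied most within the CDCP1 group it was the highest array. A trend with signal level left by the authors' normalization was argued against, because after cyclic loess its deviation was still 1.305 times the next largest of its group (95% range over resampled probes 1.29 to 1.32). A larger dose of the response shared by the CDCP1 arrays, the biological explanation the design offers, was set against covariances of differences that share no array. The amplitude of CDCP1 replicate 1 was 0.716 ± 0.31 (SD over 6 assignments of controls) of the larger of the other 2, and at most 1.03. The measure takes the arrays to deviate independently, but CDCP1 replicate 1 deviated with GFP control replicate 2 (r across probes 0.38). The ratio was 0.278 and 0.445 with that control set against CDCP1 replicate 3, and 0.922 and 1.03 with it set against CDCP1 replicate 1. The test therefore cannot decide, and a larger dose stays open. Noise added to every probe of CDCP1 replicate 1 also stays open. The ratio of its deviation to the next largest was 1.012 over the 6772 probes below background on all arrays. These were selected as dim on that array too, and the normalization fixes the width of their distribution, so this value decides nothing. Also open is a further difference of that sample, such as its culture, its RNA or its labelling. It may lie in another direction than the shared response and was not tested. On component 2, CDCP1 replicate 1 scored -13.1 and GFP control replicate 2 scored -11.7. CDCP1 replicates 2 and 3 scored 14.8 and 11.1 on it, and GFP control replicates 1 and 3 scored 2.01 and -3.05. A difference shared by CDCP1 replicate 1 and GFP control replicate 2 was not tested either.

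The labelled grouping gave 1656 called probes, and the highest count among the other splits of the 6 arrays was 0. It was 1 of 10 splits that gave as many, and 10 splits are too few for a share under 0.05.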
